A study of Homo sapiens with 21 samples.

How the data were processed

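RNA-seq counts of 21 libraries were analysed. They came from 7 drug-resistant clones of the human pancreatic ductal carcinoma line Panc-1, with 3 repeats per clone. Per the labels' protocols, Panc-1 cells from ATCC were passaged for 4 months in stepwise higher concentrations of ATUX, SMAP or Sorafenib, and the cultures that grew were cloned by serial dilution. The clones to be sequenced were chosen with the help of qRT-PCR, so that the clones were themselves picked in part on expression. All clones were kept in 8 µM of their drug. Per the labels' protocols, 500 ng of total RNA per sample entered the Illumina TruSeq Stranded mRNA kit, which selects poly-A RNA and keeps the strand.

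The deposited table holds whole-number read counts per gene and library for 58233 Ensembl genes, not normalized, per the file headers and the values. Per the submitters' processing notes, the tools were cutadapt 1.15, Bowtie2 2.3.3.1, STAR 2.5.2b, SAMtools 1.5 and featureCounts 1.5.3 with the genome build GRCh38. The order of these steps, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with close copies (such as the HLA genes, the ribosomal proteins and the mitochondrial genes) and overlapping or antisense genes carry an uncertainty from the counting. The same table gives each gene's position, length and GC content in percent as deposited by the authors. Each library's column was found by the library name in its title, and 0 columns belonged to other samples. Each clone was taken from the genotype label, its drug and dose from the treatment label and its repeat number from the title.

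Total counts per library ran from 21022621 to 27691256 (median 23026429), and mitochondrial genes took 3.19 to 5.22% of them. Values are given as CPM after TMM scaling. Where a group had 0 counts of a gene, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio of the counts is given with its 95% counting interval. Such bounds and intervals cover counting error only. Replicates of a clone were compared before they were averaged: the chi-square per degree of freedom between repeats was at least 2.26, and no pair of libraries lay within sampling noise of each other.

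Drugs were applied to cultures before cloning, and the clone was taken as a drug's replicate. For the comparisons between drugs, the counts of a clone's 3 libraries were summed, and the 7 sums were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr on the groups, quasi-likelihood fit with robust=TRUE, drug as the only factor, 18613 genes tested). All 7 clones shared 1 estimate of the spread. For the comparisons between clones of a drug, the 21 libraries were fitted by the same method with the clone as the factor (16504 genes tested). A call is an adjusted p (Benjamini-Hochberg) below 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F. Nothing in the labels says that a clone's repeats were separate cultures. P-values between clones measure only the spread between these libraries, which may be technical. Those between drugs measure only the spread between picked clones, which may share a culture of origin.

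The share of variance between clones that lay between drugs was taken on log2 CPM of clone sums (prior count 2). An exact one-sided permutation of clones over drugs tested it, with clones taken as independent. Before the data were examined, 33 gene lists, the tests and the rule for the genes named were fixed. The lists were PP2A subunits and regulators, epithelial junction and identity genes, mesenchymal and matrix genes, acinar, duct, endocrine and progenitor cell genes, cancer stem cell markers, drug efflux and uptake transporters, xenobiotic metabolism enzymes, NRF2 targets, cholesterol biosynthesis and uptake, fatty acid synthesis, integrated stress response targets, endoplasmic reticulum chaperones, ERK pathway output, receptor tyrosine kinases and RAF kinases, G1 to S and replication genes, G2 and mitosis genes, p53 targets, ribosome biogenesis, ribosomal proteins, interferon response, antigen presentation, NF-kB targets and cytokines, hypoxia and glycolysis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, YAP and TEAD targets, WNT targets, markers of stromal fibroblasts, immune cells and endothelial cells, along with dissociation and immediate early genes. All 889 listed names were found in the table, 10 of them by Ensembl ID. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over the lists) and again with a correlation estimated for each list.

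The genes named are, for each drug comparison and direction, the 10 called genes with the largest log2 fold change among those with a mean of at least 5 CPM in the higher drug and no overlap between the libraries of the drugs, and 5 per direction for each clone comparison by the same rule. Genes without a symbol or with clone-based or readthrough names were passed over. Besides these the rule takes the PP2A subunits, the 4 called members of each list with the largest change, and for lists without a call up to 4 members with the highest mean CPM. Where the text names only part of these, those that kept their call with each clone left out were preferred, a choice made after the values were seen. Some genes that the rule takes are not reported here. Of the genes that the rule takes by size of change, 8 of 20 kept their call without each clone in turn between ATUX and SMAP, 14 of 20 between ATUX and Sorafenib and 19 of 20 between SMAP and Sorafenib. Of the other called list members that it takes, 22 of 78, 49 of 111 and 63 of 122 kept it in the same order.

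The alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, stricter thresholds, limma-voom on the sums and on the libraries with the clone as a random block, the 21 libraries in place of the sums, fry in place of camera between drugs, each clone or library left out, only the 6 libraries compared, and the repeat number or the letter in the library name as a block. The newer edgeR quasi-likelihood fit, the 6-library fit with the repeat number as a block fry between clones, a run without the third libraries of both ATUX clones and a run without the third library of Sor9H were added after seeing the data. Repeat numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their clone means. It was 0.122, 0.154 and 0.21 for the 3 pairs of ATUX8H and ATUX9D, which therefore count as paired by number. It was 0.102, 0.0794 and 0.081 for Sor6G and Sor9H and between -0.0434 and 0.0374 for the SMAP clones. Neither set was counted as paired. The Sorafenib values were all positive, so a pairing of Sor6G and Sor9H by number cannot be excluded. A pairing of the ATUX clones would rest on the data alone, since the labels give only the numbers. The block moved the ATUX8H against ATUX9D count from 7609 to 7713 genes.

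The fits were tested on simulated counts in which 67, 67 and 66 genes were changed by each of 3 known folds. Between drugs, at 18127 to 18148 genes per step, 20.9 to 28.4% of genes changed by a fold of 2 were recovered, 70.1 to 74.6% at a fold of 4 and 89.4 to 95.5% at a fold of 8, with 22, 19 and 16 false calls of 146, 147 and 142 for ATUX against SMAP, ATUX against Sorafenib and SMAP against Sorafenib. Between clones, at 15953 to 15993 genes per step, 74.6 to 88.1% were recovered at a fold of 1.5 and 95.5 to 100% at a fold of 2, with 9 to 17 false calls of 191 to 201. In each drug comparison the share of false calls was above the adjusted p threshold of a call. Between clones this held in all comparisons but SMAP9C against SMAP6G. Calls may therefore include more false ones than the threshold implies. Fewer genes were changed in the simulation than were called in the real data, so these shares may not carry over.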

Results

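Gene expression was measured by RNA-seq in 7 drug-resistant clones of Panc-1, an established human pancreatic ductal carcinoma cell line. ATUX8H and ATUX9D had been grown out under ATUX, SMAP8D, SMAP9C and SMAP6G under SMAP, and Sor6G and Sor9H under Sorafenib, an inhibitor of RAF and VEGF receptor kinases. The series' design text speaks of activators of PP2A, a serine/threonine phosphatase, and names these 3 drugs. The title asks how continued exposure to them affects gene expression. Each clone was sampled in 3 libraries while in 8 µM of its drug, and the protocol gives an IC50 in Panc-1 of 6 to 10 µM for Sorafenib, ATUX and a drug that it calls SMAP2, where the other labels say SMAP. Untreated Panc-1 cells were not analysed here, so every value below compares resistant clones with each other, and none measures a change from the untreated line. Libraries held 21022621 to 27691256 counts (median 23026429). CPM are means ± SD over the clones of a drug (n = 2 ATUX, 3 SMAP and 2 Sorafenib clones) or over the libraries of a clone (n = 3), and log2 fold changes are edgeR estimates ± SE.

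Clones of the same drug lay closer to each other than to clones of another drug. The root mean square log2 difference was 0.709 on average between SMAP clones (0.654 to 0.743), 0.886 between the ATUX clones and 0.62 between the Sorafenib clones. It was 1.18 between ATUX and SMAP clones (1.11 to 1.29), 1.44 between ATUX and Sorafenib clones (1.33 to 1.54) and 1.56 between SMAP and Sorafenib clones (1.48 to 1.63). Of the variance between clones, 77.56% lay between drugs. This was the highest share of all ways to part 7 clones into groups of 2, 2 and 3, of which the next gave 69.11% and the median 30.26% (exact permutation test, one-sided, p = 0.00952, the smallest this design can give). Without SMAP8D, SMAP9C or SMAP6G the shares were 79.75, 79.25 and 81.45%, with an exact p of 0.0667, again the smallest possible.

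**Figure D1:**
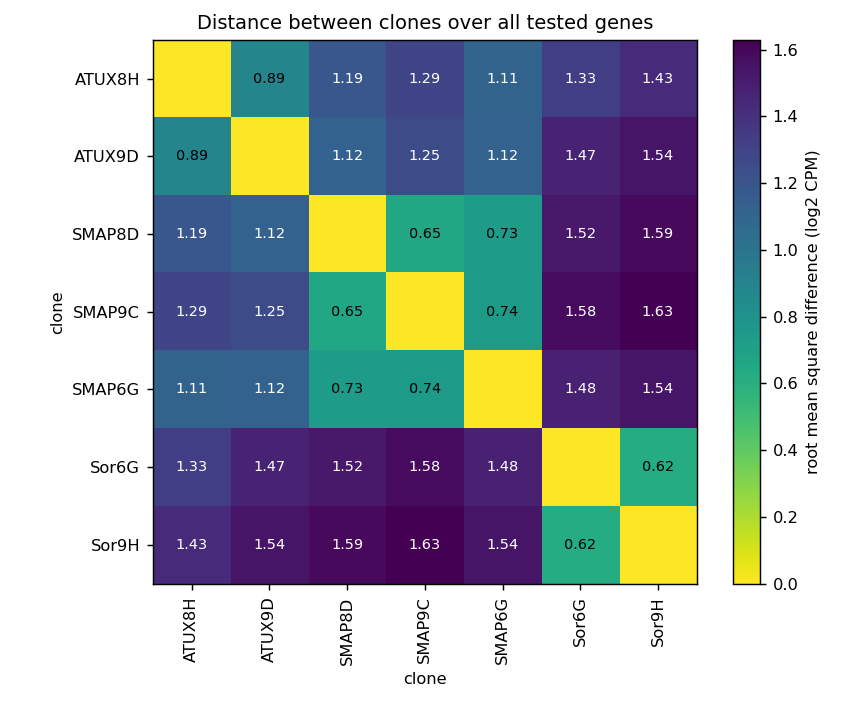
Root mean square difference in log2 CPM between each pair of the 7 clones, with clones ordered by drug and darker cells for larger differences. Pairs of clones of the same drug lie between 0.62 and 0.886, and pairs from different drugs between 1.11 and 1.63.

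PPP2CA (ENSG00000113575, GRCh38 chromosome 5, 134194334 to 134226142, minus strand), which encodes the PP2A catalytic subunit alpha, was higher in the ATUX and the SMAP clones than in the Sorafenib clones. It was at 190.6 ± 23.4 CPM in the ATUX clones, 180.7 ± 6.02 CPM in the SMAP clones and 100.7 ± 0.521 CPM in the Sorafenib clones. The log2 difference was 0.92 ± 0.12 for ATUX against Sorafenib (edgeR adjusted p = 0.00508) and 0.84 ± 0.11 for SMAP against Sorafenib (edgeR adjusted p = 0.0032). Medians were taken over chromosome 5 genes with a mean of at least 5 CPM over the clones. The 510 such genes had a median log2 of 0.48 and 0.65 in the same comparisons. The 417 of them from 50 Mb on, where PPP2CA lies, had 0.55 and 0.57. ATUX and SMAP clones did not differ in PPP2CA past the threshold (log2 = 0.08, 95% interval -0.185 to 0.339, edgeR adjusted p = 0.693). PPP2R5B, a regulatory B56 subunit, was lower at 23.6 ± 0.397 CPM with ATUX and 25.9 ± 0.891 CPM with SMAP than with Sorafenib (45.6 ± 8.34 CPM, log2 = -0.95 ± 0.15 and -0.82 ± 0.14, edgeR adjusted p = 0.00815 and 0.00599). PPP2R2C, a regulatory B55 subunit, was at 15.6 ± 10.2 CPM with ATUX, 21.9 ± 4.45 CPM with SMAP and 1.28 ± 0.553 CPM with Sorafenib. Its call held under all 17 alternatives for SMAP against Sorafenib (edgeR adjusted p = 0.00357). For ATUX against Sorafenib (edgeR adjusted p = 0.00815) it was lost without Sor9H (adjusted p = 0.0591, the highest of the alternatives, the lowest being 4.74e-14). ARPP19, an inhibitor of PP2A with B55 subunits, was lower with SMAP (182.1 CPM) than with Sorafenib (332.8 CPM, log2 = -0.87 ± 0.11, edgeR adjusted p = 0.00263).

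Of the 31 PP2A subunits and regulators tested, 2 were higher and 2 lower in ATUX than in SMAP clones, 3 higher and 2 lower in ATUX than in Sorafenib clones, and 7 higher and 3 lower in SMAP than in Sorafenib clones. The counts adjusted over the list alone were the same. STRN3, PPME1, PPP2R3B and ANP32A, the 4 genes that passed between ATUX and SMAP, each lost the call when some clone was left out. The list as a whole was not called in any drug comparison (camera adjusted p = 0.99, 0.91 and 0.871, and adjusted p = 0.993, 0.982 and 0.96 with an estimated correlation).

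**Figure D2:**
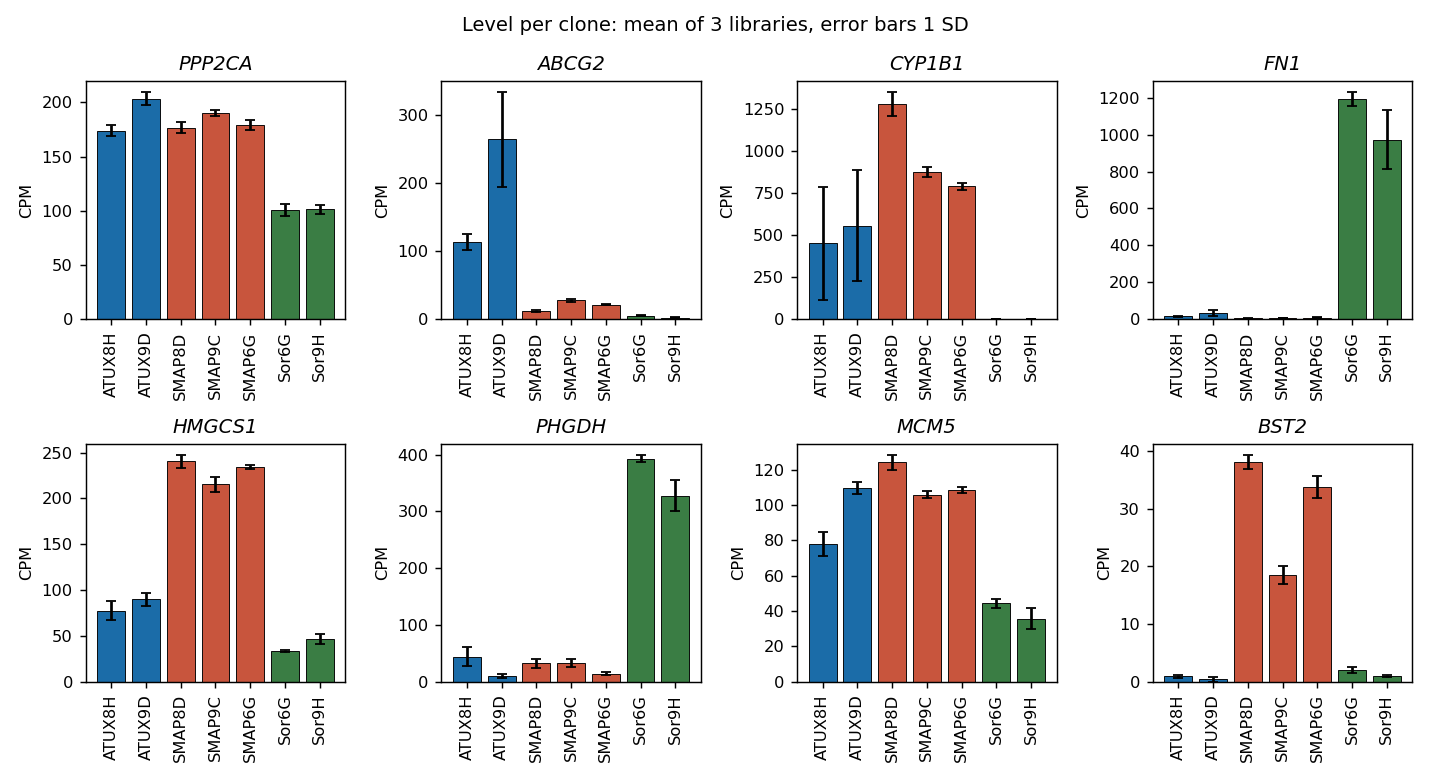
Level in CPM of 8 genes in the 7 clones, where bars are means of 3 libraries, error bars are SD and colours are drugs. PPP2CA is lowest in both Sorafenib clones, and CYP1B1 and FN1 separate the Sorafenib clones from the rest in opposite directions.

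Compared at the same 8 µM, ATUX clones had 23 of 39 interferon response genes and 11 of 24 antigen presentation genes lower than SMAP clones, and 8 of 32 epithelial genes and 6 of 21 YAP targets higher. The camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.47, 0.47, 0.883 and 0.322). Of 18613 genes, 980 were higher and 941 lower in ATUX than in SMAP clones (edgeR adjusted p under 0.05; 1921 genes, 10.3%). LEF1, a transcription factor of WNT signalling, was at 15.8 ± 3.05 CPM with ATUX and 0.0236 ± 0.00762 CPM with SMAP (log2 = 9.27 ± 0.37, edgeR adjusted p = 0.00361). ESRP2, an epithelial splicing regulator, was at 17.6 ± 9.94 against 0.0678 ± 0.0573 CPM (log2 = 8.00 ± 0.68, edgeR adjusted p = 0.00659), and RNF144B, a ubiquitin ligase, at 13.9 ± 6.28 against 0.0517 CPM (log2 = 8.01 ± 0.57, edgeR adjusted p = 0.0045). ZNF597 had 0 counts in the ATUX clones and 8.75 ± 0.59 CPM in the SMAP clones, at least 414-fold higher. SIRPA, the receptor of CD47, was at 0.535 against 41.2 ± 8.29 CPM (log2 = -6.26 ± 0.39, edgeR adjusted p = 0.0045). OLFM1 was at 0.307 against 21.8 ± 1.85 CPM, CHRNA3 at 0.0506 against 12.4 ± 4.75 CPM and NNMT, nicotinamide N-methyltransferase, at 0.0716 against 9.96 ± 4.69 CPM (edgeR adjusted p = 0.00403, 0.00704 and 0.00659). ABCG2 (ENSG00000118777, GRCh38 chromosome 4, 88090264 to 88231322, minus strand), a drug efflux transporter, was at 189.6 ± 108 CPM with ATUX and 19.8 ± 7.74 CPM with SMAP (log2 = 3.26 ± 0.53, edgeR adjusted p = 0.0182). The 16 tested genes within 1 Mb of it had a median log2 of 0.25. The ABCG2 call was lost without ATUX9D, SMAP8D or SMAP9C and without the filter (adjusted p = 0.0568, 0.0507, 0.0519 and 0.0708, range over the alternatives 1.84e-16 to 0.0708).

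Of 39 interferon response genes, 0 were higher and 23 lower with ATUX than with SMAP (0 and 34 adjusted over the list alone), with a median log2 of -1.49 (camera adjusted p = 4.76e-17, adjusted p = 0.47 with an estimated correlation and 1.4e-19 to 0.0215 under the other alternatives). The other alternatives include fry, which tests whether the genes of a list move one way and not whether they differ from other genes. IFITM1 was at 0.393 ± 0.0231 against 22.1 ± 9.51 CPM (log2 = -5.80 ± 0.49), BST2 at 0.661 ± 0.316 against 29.99 ± 10.4 CPM (log2 = -5.50 ± 0.59) and IFI44 at 1.30 ± 0.641 against 18 ± 2.21 CPM (log2 = -3.79 ± 0.35, edgeR adjusted p = 0.00619, 0.0087 and 0.00659). Of 24 antigen presentation genes, 1 was higher and 11 lower (2 and 16 adjusted over the list alone, median -1.10, camera adjusted p = 4.71e-08). For antigen presentation genes the adjusted p was 0.47 with an estimated correlation and 3.64e-10 to 0.0215 under the other alternatives. CIITA, the activator of MHC class II genes, was at 0.0935 against 4.14 ± 1.39 CPM (edgeR adjusted p = 0.0122). Of 32 epithelial junction and identity genes, 8 were higher and 1 lower (14 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 0.00106). That list had an adjusted p = 0.883 with an estimated correlation and 6.38e-08 to 0.0604 under the other alternatives, the highest with fry. The desmosomal cadherin DSC2 was at 94.2 ± 41.9 against 2.02 ± 1.30 CPM and keratin 8 (KRT8) at 5199 ± 1320 against 1072 ± 374 CPM (log2 = 5.54 ± 0.62 and 2.28 ± 0.31, edgeR adjusted p = 0.00895 and 0.0123). Of 21 YAP and TEAD targets, 6 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 0.000293). For YAP and TEAD targets the adjusted p was 0.322 with an estimated correlation and 5.46e-05 to 0.00776 under the other alternatives. CTGF was at 187 ± 15 against 20.8 ± 8.14 CPM (edgeR adjusted p = 0.0258), a call lost without ATUX8H, ATUX9D or any SMAP clone (adjusted p = 0.0557 to 0.095) and without the filter (0.11, range over the alternatives 1.01e-16 to 0.11). The iron storage gene FTH1 was at 1090 ± 133 against 4706 ± 736 CPM (log2 = -2.11 ± 0.19, edgeR adjusted p = 0.00659). HMGCS1, an enzyme of cholesterol synthesis, was at 84.4 ± 9.33 against 228.4 ± 15 CPM (log2 = -1.44 ± 0.17, edgeR adjusted p = 0.00896), in a stretch of chromosome 5 whose genes had a median log2 of -0.91.

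Of 25 ERK pathway output genes, 2 were higher and 0 lower with ATUX than with SMAP, with the same counts adjusted over the list alone (median 0.38, camera adjusted p = 0.0141). For ERK pathway output genes the adjusted p was 0.883 with an estimated correlation and 0.00114 to 0.204 under the other alternatives. Its call was lost without ATUX8H (adjusted p = 0.0741) or SMAP6G (0.0699). Of 23 p53 targets, 5 were higher and 0 lower (8 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 0.0312). For p53 targets the adjusted p was 0.47 with an estimated correlation and 0.00935 to 0.144 under the other alternatives. The call was lost without ATUX9D (0.144) or SMAP8D (0.0709). CDKN1A was at 139 ± 6.5 against 64.6 ± 18.5 CPM (edgeR adjusted p = 0.0316, and 4.81e-11 to 0.0939 over the alternatives, the highest without ATUX9D). Levels of the xenobiotic enzyme CYP1B1 (log2 = -0.97, 95% interval -1.546 to -0.396), the serine synthesis enzyme PHGDH (0.03, -1.497 to 1.556), the cytokine CCL2 (0.29, -1.341 to 1.928) and lactate dehydrogenase A (LDHA; -0.42, -0.715 to -0.116) did not differ past the threshold (edgeR adjusted p = 0.0513, 0.982, 0.819 and 0.0829). Without the third library of both ATUX clones, CYP1B1 and LDHA did pass (log2 = -1.64 and -0.56, edgeR adjusted p = 0.018 and 0.038). CYP1B1 was at 836.5 and 934.1 CPM in these 2 libraries against 252.5 to 365.3 CPM in the other 4. In the third library of both ATUX clones the YAP target CYR61 was at 696.4 and 467.6 CPM against 217.2 to 301.8 CPM in their other 4 libraries, and its call (edgeR adjusted p = 0.0335) was lost without them (0.0911, range over the alternatives 1.18e-05 to 0.111). Without the third libraries, an alternative added after seeing the data, 1879 genes were called and the ERK list was not (camera adjusted p = 0.125). The count of 1921 genes fell to 560 without SMAP9C, 705 without SMAP8D, 1005 without ATUX9D, 1131 without ATUX8H, 1124 without Sor6G and 1138 without Sor9H, and was 3472 with DESeq2 and 3933 with limma-voom and the clone as a random block. With the 21 libraries in place of the sums it was 11251, and 11310 with the repeat number as a block, where the spread is that between libraries of a clone.

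ATUX clones had 27 of 30 replication genes, 19 of 24 cholesterol genes, 9 of 21 fatty acid synthesis genes and 18 of 25 ribosome biogenesis genes higher than Sorafenib clones, and 26 of 33 integrated stress response targets lower. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.876 for each). Of the 18613 genes, 2479 were higher and 2331 lower (edgeR adjusted p under 0.05; 4810 genes, 25.8%). CYP1B1 (ENSG00000138061, GRCh38 chromosome 2, 38066973 to 38109902, minus strand) was at 496.5 ± 74.7 CPM with ATUX and 0.174 ± 0.0371 CPM with Sorafenib (log2 = 11.46 ± 0.42, edgeR adjusted p = 0.000712), a call that ended only in limma-voom with the clone as a random block (adjusted p = 0.0577, range over the alternatives 7.78e-162 to 0.0577). Without the third ATUX libraries CYP1B1 was at 311.8 ± 78.6 CPM with ATUX (log2 = 10.79, edgeR adjusted p = 0.000772). Fibronectin (FN1; ENSG00000115414, GRCh38 chromosome 2, 215360440 to 215436172, minus strand) was at 24.1 ± 14.5 against 1084 ± 161 CPM (log2 = -5.49 ± 0.75, edgeR adjusted p = 0.00593). LEF1 had 15.8 CPM with ATUX and 0 counts with Sorafenib, at least 748-fold higher, and the cadherin CDH18, on chromosome 5, 6.71 ± 0.747 CPM against 0 counts, at least 317-fold higher. The carboxylesterase CES1 was at 123.5 ± 43.5 CPM against 2 counts (ratio 8780, counting interval 2430 to 72500). CCDC8 had 0 counts with ATUX and 16.04 ± 0.668 CPM with Sorafenib, at least 752-fold higher. IGFBP2, a binding protein of insulin-like growth factors, was at 0.351 against 207.7 ± 84.9 CPM (log2 = -9.20 ± 0.59, edgeR adjusted p = 0.00132) and the homeobox gene HOXC12 at 0.549 against 155.1 ± 12.0 CPM (log2 = -8.14 ± 0.88, edgeR adjusted p = 0.00368). ABCG2 was at 189.6 against 3.13 ± 1.68 CPM (log2 = 5.92 ± 0.70, edgeR adjusted p = 0.00429), with a median of -0.15 over its neighbours.

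Of 30 G1 to S and replication genes, 27 were higher and 0 lower with ATUX than with Sorafenib (30 and 0 adjusted over the list alone, median log2 1.39, camera adjusted p = 3.3e-13). For G1 to S and replication genes the adjusted p was 0.876 with an estimated correlation and 2.09e-15 to 0.0301 under the other alternatives. CDC6, a replication licensing factor, was at 66.5 ± 7.32 against 12.1 ± 1.56 CPM and CCNE2, cyclin E2, at 46.6 ± 15.7 against 5.54 CPM (log2 = 2.46 ± 0.22 and 3.07 ± 0.42, edgeR adjusted p = 0.0026 and 0.00584). Of 24 genes of cholesterol biosynthesis and uptake, 19 were higher and 0 lower (21 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 1.32e-10). For genes of cholesterol biosynthesis and uptake the adjusted p was 0.876 with an estimated correlation and 3.53e-13 to 0.026 under the other alternatives. Of 21 fatty acid synthesis genes, 9 were higher and 3 lower (12 and 5 adjusted over the list alone, median 0.73, camera adjusted p = 0.0124). For fatty acid synthesis genes the adjusted p was 0.876 with an estimated correlation and 0.000759 to 0.0514 under the other alternatives, the lowest with fry and the highest with the 21 libraries. Fatty acid synthase (FASN) was at 959.6 ± 402 against 96.5 ± 9.46 CPM and the desaturase FADS2 at 227.4 ± 79.8 against 12.6 ± 5.51 CPM (log2 = 3.31 ± 0.30 and 4.17 ± 0.53, edgeR adjusted p = 0.00262 and 0.00491). In the third libraries of ATUX8H and ATUX9D FADS2 was at 66.7 and 143.8 CPM against 220.4 to 340.2 CPM in their other 4 libraries. Of 33 integrated stress response targets, 2 were higher and 26 lower (2 and 27 adjusted over the list alone, median -1.60, camera adjusted p = 2.2e-09). For integrated stress response targets the adjusted p was 0.876 with an estimated correlation and 3.54e-13 to 0.0261 under the other alternatives. DDIT4 was at 49.4 ± 28.3 against 491.7 ± 208 CPM (log2 = -3.32 ± 0.50, edgeR adjusted p = 0.00771). Of 25 ribosome biogenesis genes, 18 were higher and 0 lower (19 and 1 adjusted over the list alone, median 0.70, camera adjusted p = 4.89e-07). For ribosome biogenesis genes the adjusted p was 0.876 with an estimated correlation and 3.69e-09 to 0.0261 under the other alternatives. BOP1 was at 116.2 against 35.5 CPM (log2 = 1.71 ± 0.15, edgeR adjusted p = 0.00254).

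Of 33 hypoxia and glycolysis genes, 12 were higher and 2 lower with ATUX than with Sorafenib, with the same counts adjusted over the list alone (median log2 0.48, camera adjusted p = 0.00301). For hypoxia and glycolysis genes the adjusted p was 0.876 with an estimated correlation and 0.000224 to 0.0313 under the other alternatives. LDHA was at 1691 ± 49.8 against 447.5 ± 58.7 CPM (log2 = 1.92 ± 0.14, edgeR adjusted p = 0.00166). Hexokinase 2 (HK2), of the same list, was at 31.4 and 12.8 CPM in the third ATUX libraries against 4.40 to 10.1 CPM in the other 4. Of 39 interferon response genes, 1 was higher and 14 lower (2 and 15 adjusted over the list alone, median -0.53, camera adjusted p = 0.000939). For interferon response genes the adjusted p was 0.916 with an estimated correlation and 0.000183 to 0.0862 under the other alternatives, the highest with fry. IFI44 was at 1.30 against 11.4 CPM (log2 = -3.13 ± 0.35, edgeR adjusted p = 0.00379). Of 37 nuclear oxidative phosphorylation genes, 9 were higher and 3 lower (13 and 3 adjusted over the list alone, median 0.17, camera adjusted p = 0.0482). For nuclear oxidative phosphorylation genes the adjusted p was 0.916 with an estimated correlation and 0.0036 to 0.314 under the other alternatives. That call was lost without Sor6G (0.314), ATUX8H (0.0543), ATUX9D (0.16), SMAP8D (0.0571) or SMAP9C (0.0622), and without the third ATUX libraries (0.117). PPARGC1A, a coactivator of mitochondrial biogenesis, was at 0.726 against 13.0 CPM (log2 = -4.16 ± 0.42, edgeR adjusted p = 0.003). Of 13 mitochondrially encoded genes, 0 were higher and 6 lower (0 and 7 adjusted over the list alone, median -0.39, camera adjusted p = 0.0215). For mitochondrially encoded genes the adjusted p was 0.916 with an estimated correlation and 0.000997 to 0.131 under the other alternatives. The call was lost without ATUX8H (0.131) and without the third ATUX libraries (0.0521). In the third library of Sor9H mitochondrial genes took 3.58% of the counts, against 4.54 to 5.22% in the other Sorafenib libraries, and without it, an alternative added after seeing the data, the median was -0.51 (camera adjusted p = 0.0036). Of 31 G2 and mitosis genes, 4 were higher and 0 lower (0 and 0 adjusted over the list alone, median 0.62, camera adjusted p = 9.92e-05). For G2 and mitosis genes the adjusted p was 0.916 with an estimated correlation and 7.15e-15 to 0.318 under the other alternatives. The call was lost without Sor9H (median 0.20, adjusted p = 0.0646). The count of 4810 genes fell to 1430 without Sor9H, 2142 without Sor6G and 2780 without ATUX9D, and was 4857 without the third ATUX libraries. It was 12675 with the 21 libraries in place of the sums and 12712 with the repeat number as a block.

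SMAP clones had 21 of 24 cholesterol genes, 25 of 30 replication genes, 17 of 24 antigen presentation genes and 12 of 39 interferon response genes higher than Sorafenib clones, and 25 of 33 integrated stress response targets and 8 of 17 duct cell genes lower. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.738, 0.767, 0.738, 0.767, 0.738 and 0.887), and that of duct cell genes also without SMAP9C (0.0642). Of the 18613 genes, 3133 were higher and 3295 lower (edgeR adjusted p under 0.05; 6428 genes, 34.5%). CYP1B1 was at 973 ± 268 against 0.174 CPM (log2 = 12.43 ± 0.43, edgeR adjusted p = 0.000465) and FN1 at 4.10 ± 2.76 against 1084 ± 161 CPM (log2 = -8.05 ± 0.71, edgeR adjusted p = 0.0012). The adhesion molecule NCAM1 had 35.8 ± 12.9 CPM with SMAP and 0 counts with Sorafenib, at least 1710-fold higher, and CDH18, on the short arm of chromosome 5, 35.0 ± 9.63 CPM against 0 counts, at least 1670-fold higher. ZNF385D was at 54.2 ± 9.25 CPM against 1 count (ratio 7790, counting interval 1400 to 308000). The matrix gene TNC was at 270.1 ± 231 against 0.0562 CPM (log2 = 12.19 ± 1.67, edgeR adjusted p = 0.0036). HOXC12 was at 0.0872 against 155.1 ± 12.0 CPM (log2 = -10.79 ± 0.85, edgeR adjusted p = 0.00103). PPARGC1A was at 0.0239 against 13.0 ± 1.88 CPM, MAP2K6, a kinase that activates p38, at 0.0661 against 39.6 ± 3.22 CPM, the prostaglandin transporter SLCO2A1 at 0.0373 against 17.1 ± 5.47 CPM and the fatty acid elongase ELOVL6 at 0.119 ± 0.0124 against 48.6 ± 20.2 CPM (edgeR adjusted p = 0.000465, 0.00275, 0.00159 and 0.00632). Haem oxygenase 1 (HMOX1) was at 199.8 ± 27.5 against 23.4 ± 9.01 CPM (edgeR adjusted p = 0.00125).

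Of 24 genes of cholesterol biosynthesis and uptake, 21 were higher and 0 lower with SMAP than with Sorafenib (22 and 1 adjusted over the list alone, median log2 1.32, camera adjusted p = 1.52e-09). For genes of cholesterol biosynthesis and uptake the adjusted p was 0.738 with an estimated correlation and 1.36e-11 to 0.00991 under the other alternatives. INSIG1 was at 115.9 ± 19.9 against 20.95 ± 4.87 CPM (log2 = 2.47 ± 0.22, edgeR adjusted p = 0.00117), and HMGCS1 at 228.4 ± 15 against 40.0 ± 8.98 CPM (log2 = 2.51 ± 0.18, edgeR adjusted p = 0.000716) in a stretch of chromosome 5 with a median of 0.97. Of 21 fatty acid synthesis genes, 11 were higher and 4 lower (11 and 5 adjusted over the list alone, median 1.20, camera adjusted p = 0.0187). For fatty acid synthesis genes the adjusted p was 0.738 with an estimated correlation and 0.000276 to 0.079 under the other alternatives, the lowest with fry and the highest with the 21 libraries. FASN was at 631.7 ± 49.0 against 96.5 CPM (log2 = 2.71 ± 0.28, edgeR adjusted p = 0.00163). Of 30 G1 to S and replication genes, 25 were higher and 0 lower (28 and 0 adjusted over the list alone, median 1.248, camera adjusted p = 4.18e-10). For G1 to S and replication genes the adjusted p was 0.767 with an estimated correlation and 4.25e-12 to 0.0239 under the other alternatives. Members included CDC6 at 43.8 against 12.1 CPM (log2 = 1.86 ± 0.21, edgeR adjusted p = 0.00198). Of 25 ribosome biogenesis genes, 14 were higher and 1 lower, with the same counts adjusted over the list alone (median 0.53, camera adjusted p = 0.000466). For ribosome biogenesis genes the adjusted p was 0.767 with an estimated correlation and 6.5e-06 to 0.0215 under the other alternatives. Of 33 integrated stress response targets, 1 was higher and 25 lower (1 and 26 adjusted over the list alone, median -1.48, camera adjusted p = 1.05e-09). For integrated stress response targets the adjusted p was 0.738 with an estimated correlation and 4.19e-13 to 0.0127 under the other alternatives. PHGDH was at 26.1 ± 10.7 against 360.3 ± 47.9 CPM and ALDH1L2, a mitochondrial folate enzyme, at 1.248 against 160.5 ± 35.7 CPM (log2 = -3.79 ± 0.66 and -7.00 ± 0.82, edgeR adjusted p = 0.00746 and 0.00246).

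Of 24 antigen presentation genes, 17 were higher and 0 lower with SMAP than with Sorafenib (18 and 0 adjusted over the list alone, median log2 1.31, camera adjusted p = 5.68e-07). For antigen presentation genes the adjusted p was 0.738 with an estimated correlation and 4.3e-08 to 0.00991 under the other alternatives. For CIITA the log2 was 7.52 ± 0.88 and for HLA-F 4.00 ± 0.53 (edgeR adjusted p = 0.00226 and 0.00313). Of 39 interferon response genes, 12 were higher and 2 lower, with the same counts adjusted over the list alone (median 0.65, camera adjusted p = 0.000583). For interferon response genes the adjusted p was 0.767 with an estimated correlation and 7.41e-05 to 0.0522 under the other alternatives, the highest with fry. IFITM1 was at 22.1 against 0.140 CPM and BST2 at 29.99 against 1.5 CPM (log2 = 7.28 ± 0.54 and 4.32 ± 0.55, edgeR adjusted p = 0.00074 and 0.00302). Of 33 hypoxia and glycolysis genes, 16 were higher and 3 lower, with the same counts adjusted over the list alone (median 0.58, camera adjusted p = 0.00102). For hypoxia and glycolysis genes the adjusted p was 0.738 with an estimated correlation and 0.000246 to 0.0134 under the other alternatives. Members included LDHA at 2255 ± 73 against 447.5 CPM (log2 = 2.33 ± 0.14, edgeR adjusted p = 0.00049). Of 13 mitochondrially encoded genes, 0 were higher and 8 lower (0 and 9 adjusted over the list alone, median -0.53, camera adjusted p = 0.00247). For mitochondrially encoded genes the adjusted p was 0.767 with an estimated correlation and 0.000463 to 0.0492 under the other alternatives, the lowest without the third library of Sor9H (median -0.62), which had 3.58% mitochondrial counts against 3.44 to 4.22% in the SMAP libraries. Members included MT-ND2 at 1409 against 2561 CPM (log2 = -0.86 ± 0.13, edgeR adjusted p = 0.00438). Of 17 duct cell genes, 1 was higher and 8 lower (1 and 9 adjusted over the list alone, median -1.75, camera adjusted p = 0.0247). For duct cell genes the adjusted p was 0.887 with an estimated correlation and 0.0165 to 0.0642 under the other alternatives. The call was lost without SMAP9C (0.0642). The trefoil factor TFF2 had 0 counts with SMAP and 2.68 ± 0.24 CPM with Sorafenib (edgeR adjusted p = 0.00291). Of 31 G2 and mitosis genes, 4 were higher and 0 lower (0 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.00965). For G2 and mitosis genes the adjusted p was 0.895 with an estimated correlation and 7.24e-11 to 0.937 under the other alternatives. The call was lost without Sor9H (median -0.006, adjusted p = 0.937). The count of 6428 genes fell to 2761 without Sor9H and 3364 without Sor6G. It was 13068 with the 21 libraries in place of the sums and 13118 with the repeat number as a block.

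**Figure D3:**
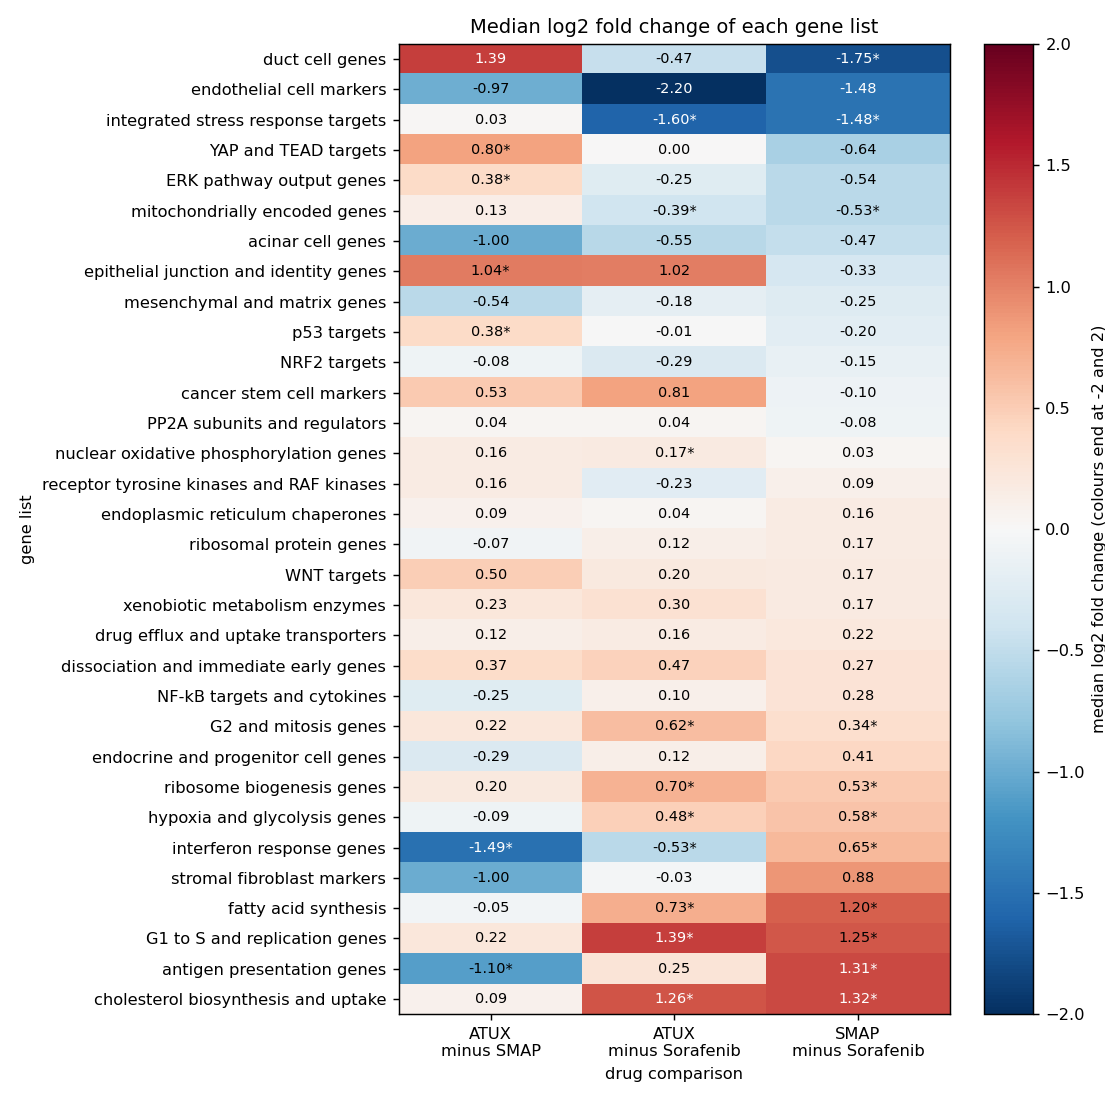
Median log2 fold change of the tested members of 32 gene lists in the 3 drug comparisons, with colours that end at -2 and 2 and asterisks for a camera adjusted p under 0.05. The integrated stress response list is at -1.60 and -1.48 against Sorafenib, and the interferon list at -1.49 for ATUX against SMAP.

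Of the pairs of clones of the same drug, the ATUX clones lay farthest apart. Between ATUX8H and ATUX9D, 3814 of 16504 genes were higher and 3795 lower in ATUX8H (edgeR adjusted p under 0.05), and 2084 of them differed by a log2 of at least 1, with 1521 higher and 563 lower. Of 31 epithelial genes, 22 were higher and 4 lower in ATUX8H, with the same counts adjusted over the list alone (median 0.69, camera adjusted p = 8.34e-05). For epithelial genes the adjusted p was 0.0206 with an estimated correlation and 8.56e-10 to 5.53e-05 under the other alternatives, the lowest with fry. E-cadherin (CDH1) was at 76.2 ± 44.6 against 7.12 ± 2.95 CPM (edgeR adjusted p = 8.32e-06). In the third libraries CDH1 was at 24.98 CPM in ATUX8H and 3.724 CPM in ATUX9D, against 97.02 and 106.6 and against 8.614 and 9.024 CPM in the others. Of 14 duct cell genes, 12 were higher and 0 lower, also adjusted over the list alone (median 1.58, camera adjusted p = 0.000182). For duct cell genes the adjusted p was 0.0206 with an estimated correlation and 1.07e-09 to 0.000218 under the other alternatives, the lowest with fry. Members included AGR2 at 111.5 against 31.99 CPM. Of 33 integrated stress response targets, 18 were higher and 3 lower, also adjusted over the list alone (median 0.49, camera adjusted p = 0.00709). For integrated stress response targets the adjusted p was 0.728 with an estimated correlation and 0.00432 to 0.021 under the other alternatives, with NUPR1 at 37.6 ± 5.60 against 3.96 ± 0.653 CPM. Of 30 replication genes 0 were higher and 24 lower (0 and 26 adjusted over the list alone, median -0.43, camera adjusted p = 9.91e-10). For replication genes the adjusted p was 0.312 with an estimated correlation and 2.02e-09 to 1.41e-06 under the other alternatives, the highest with fry. Of 31 G2 and mitosis genes 0 were higher and 26 lower (0 and 27 adjusted over the list alone, median -0.33, camera adjusted p = 7.18e-09). For G2 and mitosis genes the adjusted p was 0.48 with an estimated correlation and 3.55e-10 to 2.92e-05 under the other alternatives, the highest with fry. Of 23 antigen presentation genes 0 were higher and 10 lower, also adjusted over the list alone (median -0.32, camera adjusted p = 0.0347). For antigen presentation genes the adjusted p was 0.728 with an estimated correlation and 0.0018 to 0.218 under the other alternatives, the lowest with fry. The call was lost without the third libraries (0.218). PKD1L1 was at 44.8 ± 16 against 0.329 CPM (log2 = 7.05 ± 0.38, edgeR adjusted p = 2.53e-11), and CD69, an early lymphocyte activation antigen, at 8.40 ± 3.93 CPM against 0 counts, at least 200-fold higher. The cadherin CDH10, on chromosome 5, was at 0.929 against 33.7 ± 5.26 CPM (log2 = -5.18 ± 0.19, edgeR adjusted p = 1.44e-14). Without the third libraries 7823 genes were called, and 5056 with only the 6 libraries compared (5964 with the repeat number as a block), where the other pairs of clones had 6191 to 7900.

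Between Sor6G and Sor9H, 2645 genes were higher and 2916 lower in Sor6G (edgeR adjusted p under 0.05), 907 of them by a log2 of at least 1 (431 higher and 476 lower). The third library of Sor9H had a chi-square per degree of freedom of 15.58 and 13.96 against the other 2 of its clone, which had 4.52 between them, and 3.58% mitochondrial counts against 5.06 and 5.22%. Without it 2434 genes were higher and 2378 lower. Of the 12 lists called by camera with the preset correlation, 11 passed without it, in a test chosen after seeing the data. All 31 G2 and mitosis genes were higher in Sor6G, also adjusted over the list alone (median 0.92, camera adjusted p = 7.4e-36, adjusted p = 0.0731 with an estimated correlation and 3.42e-37 to 1.69e-09 under the other alternatives). CENPE, a kinetochore motor, was at 102.3 ± 3.39 against 41.9 ± 8.28 CPM. Integrated stress response targets (19 higher and 0 lower of 33, 20 and 0 adjusted over the list alone), ribosome biogenesis genes (18 and 0 of 25, 20 and 0 alone) and replication genes (19 and 1 of 30, 20 and 1 alone) had more genes higher than lower (camera adjusted p = 2.53e-11, 1.2e-06 and 1.71e-05, adjusted p = 0.442, 0.42 and 0.599 with an estimated correlation). Cholesterol genes (0 and 17 of 24, 0 and 18 alone) and nuclear oxidative phosphorylation genes (0 and 19 of 37, 0 and 19 alone) had more lower than higher (camera adjusted p = 2.53e-05 and 1.23e-05, adjusted p = 0.442 and 0.599 with an estimated correlation). Endoplasmic reticulum chaperones (10 and 2 of 23), antigen presentation (10 and 1 of 23), interferon (13 and 3 of 39) and NRF2 genes (9 and 4 of 27), with the same counts alone, had more genes higher than lower. Of 33 ribosomal protein genes 0 passed as higher, 5 as lower and 28 did not pass (0 and 3 alone, median -0.09), and of 19 immediate early genes 1 was higher and 10 lower (2 and 12 alone). Their tests passed in the same order (camera adjusted p = 0.00758, 0.00758, 0.0203, 0.0281, 0.0387 and 0.0159, adjusted p = 0.442, 0.599, 0.599, 0.633, 0.919 and 0.599 with an estimated correlation). The call of ribosomal protein genes was also lost with fry (adjusted p = 0.248) and without the third library of Sor9H (0.716, median -0.01), with 0.0204 to 0.919 over the alternatives. MX2, an interferon-induced GTPase, was at 16.4 ± 2.07 against 2.08 ± 0.294 CPM (log2 = 2.98 ± 0.18, edgeR adjusted p = 4.02e-11), and the myosin MYO1D at 0.191 against 39.9 ± 2.97 CPM (log2 = -7.70 ± 0.29, edgeR adjusted p = 1.4e-15).

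Among the SMAP clones, SMAP8D had 22 of 39 interferon response genes and 12 of 24 NF-kB targets higher than SMAP9C (5 and 0 lower), and 24 and 12 higher than SMAP6G (1 and 2 lower). The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.233 and 0.371 against SMAP9C, 0.388 and 0.779 against SMAP6G). Against SMAP9C, 2850 genes were higher and 2948 lower in SMAP8D (edgeR adjusted p under 0.05), 1017 of them by a log2 of at least 1 (588 higher and 429 lower). Of 39 interferon genes 22 were higher and 5 lower, also adjusted over the list alone (median 0.52, camera adjusted p = 1.2e-08, adjusted p = 0.233 with an estimated correlation and 1.42e-08 to 7.06e-07 under the other alternatives), with MX1 at 22.6 ± 2.48 against 3.70 ± 0.545 CPM. Of 24 NF-kB targets 12 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 2.75e-05, adjusted p = 0.371 with an estimated correlation). Replication (28 and 0 of 30, 29 and 0 alone), mitosis (27 and 0 of 31, also alone) and cholesterol genes (15 and 2 of 24, 18 and 3 alone) had more genes higher than lower (camera adjusted p = 1.52e-15, 1.56e-11 and 0.000142, adjusted p = 0.233, 0.371 and 0.393 with an estimated correlation). Ribosomal protein genes (0 and 30 of 33, 0 and 31 alone) and hypoxia genes (2 and 18 of 31, 2 and 20 alone) had more lower than higher (camera adjusted p = 1.26e-11 and 0.000149, adjusted p = 0.393 and 0.371 with an estimated correlation). Of 23 chaperones 8 were higher and 2 lower, and of 19 immediate early genes 1 was higher and 10 lower, with the same counts alone (camera adjusted p = 0.0376 and 9e-04, adjusted p = 0.393 for both with an estimated correlation). AGR2, a protein disulfide isomerase, was at 22.04 ± 3.15 against 0.0692 CPM (log2 = 8.16 ± 0.76, edgeR adjusted p = 7.39e-07), collagen COL11A1 at 139.6 ± 11.6 against 0.565 CPM (log2 = 7.95 ± 0.59, edgeR adjusted p = 7.32e-08) and the prolactin receptor PRLR, on the short arm of chromosome 5, at 13.9 against 87.6 ± 9.07 CPM (log2 = -2.65 ± 0.11, edgeR adjusted p = 1.41e-14).

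Against SMAP6G, 2836 genes were higher and 2905 lower in SMAP8D (edgeR adjusted p under 0.05), 1134 of them by a log2 of at least 1 (669 higher and 465 lower). Of 39 interferon genes 24 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 7.36e-09, adjusted p = 0.388 with an estimated correlation and 8.48e-09 to 2.45e-06 under the other alternatives). Of 10 stromal fibroblast markers 7 were higher and 1 lower (8 and 1 adjusted over the list alone, median 1.86, camera adjusted p = 0.00549, adjusted p = 0.61 with an estimated correlation). Lumican (LUM) was at 5.29 ± 0.753 against 0.316 ± 0.122 CPM, and COL1A1, COL3A1 and THY1 of that list are also mesenchymal genes. ERK output genes (12 and 3 of 25, also alone), NF-kB targets (12 and 2 of 24, 13 and 2 alone), replication (18 and 0 of 30, 20 and 0 alone) and mitosis genes (17 and 0 of 31, 18 and 0 alone) had more genes higher than lower and hypoxia genes (2 and 13 of 31, also alone) more lower (camera adjusted p = 0.00125, 0.00549, 7.51e-07, 0.000106 and 0.00109, adjusted p = 0.78, 0.779, 0.63, 0.78 and 0.61 with an estimated correlation). The ERK phosphatase DUSP6 was at 9.62 ± 1.41 against 1.82 ± 0.182 CPM. The tight junction gene CLDN4 was at 5.26 ± 0.593 against 148.8 ± 4.89 CPM (log2 = -4.82 ± 0.09, edgeR adjusted p = 2.7e-21), and DNER at 1.18 against 54.6 ± 4.92 CPM (log2 = -5.53 ± 0.18, edgeR adjusted p = 3.41e-17).

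Between SMAP9C and SMAP6G, 3301 genes were higher and 3254 lower in SMAP9C (edgeR adjusted p under 0.05), 1283 of them by a log2 of at least 1 (673 higher and 610 lower). Of 10 stromal fibroblast markers 7 were higher and 1 lower in SMAP9C, also adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.642 with an estimated correlation), with LUM at 9.83 ± 1.45 against 0.316 CPM. Of 31 epithelial genes 4 were higher and 12 lower (4 and 14 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.463 with an estimated correlation), with CLDN4 at 24.7 against 148.8 CPM. Ribosomal protein genes (19 and 0 of 33, 20 and 0 alone) and integrated stress response targets (14 and 2 of 33, 15 and 2 alone) had more genes higher than lower, and cholesterol genes (2 and 17 of 24, 3 and 18 alone) and replication genes (2 and 20 of 30, 3 and 22 alone) more lower (camera adjusted p = 1.07e-05, 0.01, 7.13e-05 and 0.000211, adjusted p = 0.876, 0.876, 0.642 and 0.828 with an estimated correlation). NRF2 targets (3 and 12 of 27, also alone), mitosis genes (0 and 11 of 31, 0 and 10 alone) and nuclear oxidative phosphorylation genes (3 and 15 of 37, also alone) had more genes lower than higher, and immediate early genes (9 and 1 of 19, 9 and 2 alone) more higher. Their tests passed in the same order (camera adjusted p = 0.01, 0.0141, 0.0203 and 0.0127, adjusted p = 0.828, 0.876, 0.876 and 0.828 with an estimated correlation). The calls of integrated stress response targets and mitosis genes were also lost with fry (adjusted p = 0.0666 and 0.0612, and 0.00385 and 0.0158 with the block). The NRF2 targets had a median of -0.20 but a mean of 0.02. COL23A1, on chromosome 5, was at 84.2 ± 3.32 against 0.2996 CPM (log2 = 8.11 ± 0.20, edgeR adjusted p = 6.68e-19). The basement membrane collagen COL4A2 was at 0.125 against 12.1 CPM (log2 = -6.64 ± 0.50, edgeR adjusted p = 1.13e-08), and COL4A1 at 1 count against 7.61 ± 0.855 CPM (ratio 530, counting interval 94.6 to 21000).

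The other lists were not called by camera with the preset correlation in any drug comparison of the clone sums. With fry, which tests whether a list moves one way and not against other genes, mesenchymal genes passed for ATUX against SMAP (adjusted p = 0.0458, and 0.0162 to 0.47 over the alternatives) and against Sorafenib (0.0493, up to 0.916). By fry alone kinases passed for ATUX (adjusted p = 0.0493, up to 0.951) and SMAP (0.0215, up to 0.981) against Sorafenib, and endocrine genes for ATUX against SMAP (0.0375, up to 0.998). For SMAP against Sorafenib, YAP and TEAD targets also passed with fry (adjusted p = 0.00671, camera 0.0505), with 3 of 21 higher and 8 lower. So did p53 targets (fry adjusted p = 0.0321, camera 0.232), with 2 of 23 higher and 5 lower. Some lists passed with camera under other alternatives, a part of them chosen after seeing the data. For ATUX against SMAP these were ribosomal protein genes under 4 of 12 alternatives (adjusted p = 0.00583 to 0.993), NRF2 targets under 3 (0.0304 to 0.993), mesenchymal genes with 21 libraries and without SMAP9C, stromal markers without SMAP6G (0.00927 to 0.993) and stem cell markers without ATUX9D (0.0206 to 0.993). Immediate early genes passed without Sor9H for ATUX and SMAP against Sorafenib (camera adjusted p = 0.00781 and 0.0331, up to 0.916 and 0.887). For SMAP against Sorafenib ribosomal protein genes passed under 3 of 12 (0.0256 to 0.96) and endothelial markers without Sor6G (0.0379 to 0.887). Counts below are genes higher and lower for ATUX against SMAP, ATUX against Sorafenib and SMAP against Sorafenib, with those adjusted over the list alone in parentheses (edgeR). Of 35 mesenchymal and matrix genes they were 2 and 4 (2 and 6), 7 and 8 (8 and 11), and 11 and 8 (12 and 8), with vimentin (VIM) at 3316, 4099 and 2569 CPM in ATUX, SMAP and Sorafenib clones. Of 28 receptor tyrosine kinases and RAF kinases they were 2 and 1 (2 and 1), 5 and 10 (10 and 12), and 4 and 9 (4 and 10), with EGFR at 314.8, 414.5 and 381.7 CPM. Of 22 efflux and uptake transporters they were 2 and 3 (2 and 4), 5 and 5 (8 and 5), and 8 and 4 (8 and 5), with the nucleoside transporter SLC29A1 at 686.4, 372.4 and 298.9 CPM. Of 25 xenobiotic enzymes they were 2 and 2 (3 and 4), 4 and 5 (7 and 5), and 3 and 4 (3 and 4). Of 27 NRF2 targets they were 0 and 3 (0 and 3), 2 and 4 (2 and 4), and 5 and 7 (6 and 7). Of 23 endoplasmic reticulum chaperones they were 0 and 0 (0 and 0), 6 and 1 (6 and 1), and 5 and 3 (5 and 3), with HSPA5 at 713.4, 799.2 and 831.3 CPM. Of 33 ribosomal proteins they were 0 and 3 (0 and 3), 3 and 2 (2 and 1), and 5 and 0 (3 and 0). Of 28 NF-kB targets they were 1 and 1 (1 and 0), 4 and 5 (5 and 5), and 9 and 4 (9 and 4), with CSF1 at 451.0, 635.4 and 111.6 CPM. Of 16 WNT targets they were 4 and 2 (4 and 2), 3 and 3 (3 and 3), and 5 and 2 (6 and 3), with DKK1 at 772.1, 316.8 and 298.7 CPM. Of 14 cancer stem cell markers they were 0 and 0 (3 and 0), 3 and 1 (3 and 1), and 3 and 1 (3 and 1), with CD44 at 2777, 1648 and 801.8 CPM. Of 22 immediate early genes they were 1 and 2 (2 and 3), 5 and 3 (6 and 3), and 5 and 3 (6 and 3), with BAG3 at 204.7, 392.0 and 144.5 CPM.

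Markers of other cell types were low or mixed. Of 6 acinar genes the counts were 1 and 0 (1 and 2), 1 and 2 (1 and 2), and 1 and 1 (1 and 1), with GATA4 at 29.2, 25.1 and 48.3 CPM. Of 10 endocrine and progenitor genes they were 0 and 2 (3 and 3), 0 and 0 (0 and 0), and 4 and 4 (4 and 4), with SCG2 at 8.76, 94.8 and 46.1 CPM. Of 10 stromal fibroblast markers they were 0 and 0 (0 and 0), 1 and 1 (1 and 1), and 3 and 1 (4 and 1), with COL1A1 at 38.3, 121.1 and 11.8 CPM. Of 5 endothelial markers they were 1 and 0 (1 and 1), 0 and 0 (0 and 0), and 0 and 2 (1 and 2), with ESAM at 4.91, 1.62 and 3.38 CPM. The immune cell markers had 4 tested genes and were not tested as a list, and LAPTM5 was at 2.32, 0.945 and 1.20 CPM. The camera adjusted p of these lists ran from 0.169 to 0.99, and that of the lists of the paragraph before from 0.0874 to 0.99. The median, mean and test of a list differed in sign in 22 of 96 drug comparisons of a list, of which 0 were called. These were PP2A, transporter, xenobiotic, fatty acid, chaperone, hypoxia and endothelial genes for ATUX against SMAP, and acinar, endocrine, xenobiotic, kinase and p53 genes for ATUX against Sorafenib. For SMAP against Sorafenib they were PP2A, epithelial, mesenchymal, acinar, endocrine, stem cell, xenobiotic, kinase, nuclear oxidative phosphorylation and WNT genes. Between clones the signs differed in 35 of 155, and the NRF2 list of SMAP9C against SMAP6G was the called one. With genes at 0 counts placed at their bound, the list medians that moved were those of antigen presentation for ATUX against Sorafenib (0.25 to 0.12) and WNT targets for SMAP against Sorafenib (0.17 to 0.14).

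Median levels over chromosomes, and over parts of them, differed between clones. The medians cover genes with a mean of at least 5 CPM over the clones. The median log2 difference of chromosome 5 genes from the mean of the other clones was -0.48 in Sor6G and -0.49 in Sor9H, and 0.15, 0.24 and 0.36 in SMAP8D, SMAP9C and SMAP6G. Chromosome 7 was at 0.33 and 0.40 in the Sorafenib clones. Chromosome X was at 0.51 in ATUX8H and -0.53 in ATUX9D, but its first 25 Mb at -0.43 and -0.42. In the first 50 Mb of chromosome 5 the bin medians were -1.04 and -0.91 for ATUX against SMAP, 0.29 and -0.002 for ATUX against Sorafenib and 1.29 and 0.97 for SMAP against Sorafenib. From 50 Mb on they were -0.09 to 0.03, 0.39 to 0.59 and 0.42 to 0.68. Some bins of other autosomes shifted as much or more. The bin of chromosome 13 from 100 to 125 Mb was at -1.15 in Sor6G and -1.17 in Sor9H. Its medians were 1.38 for ATUX and 1.47 for SMAP against Sorafenib. On chromosome 17 from 25 to 50 Mb these were 0.74 and 0.65, and on chromosome 18 from 50 to 75 Mb 0.71 and 0.69. Other bins went the other way, such as chromosome 7 from 75 to 100 Mb at -0.54 and -0.71.

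**Figure D4:**
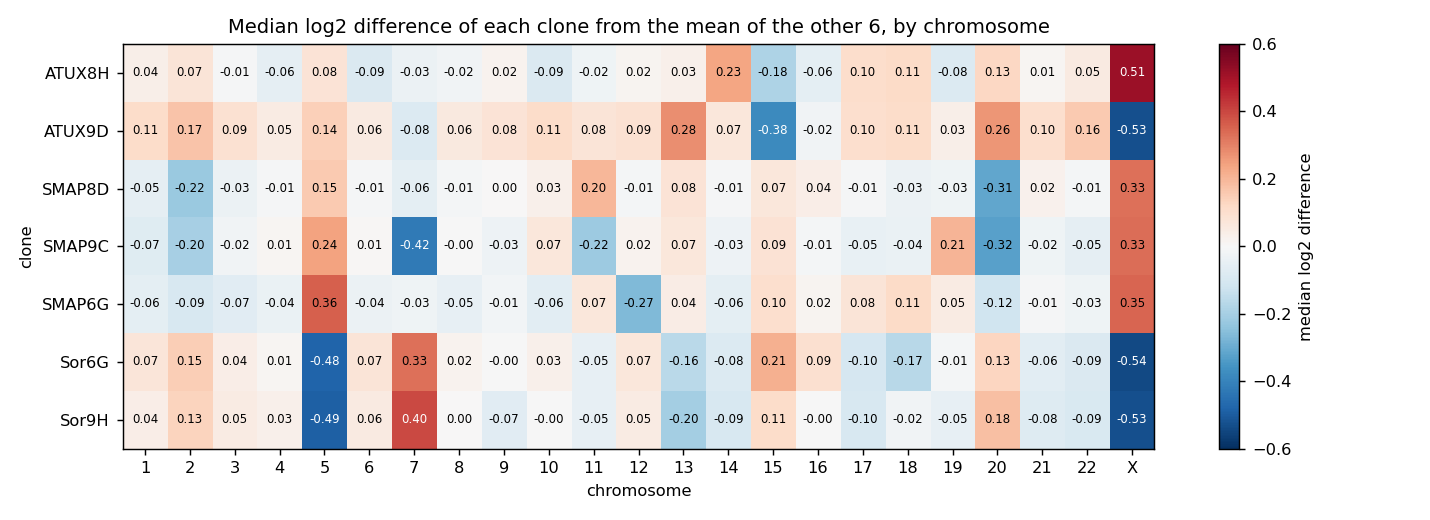
Median log2 difference of each clone from the mean of the other 6 over genes of chromosomes 1 to 22 and X, where colour gives the median. Genes had a mean of at least 5 CPM over the clones. Chromosome 5 is at -0.48 and -0.49 in the Sorafenib clones and at 0.15 to 0.36 in the SMAP clones.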

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

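The tests of normalization, of a shift of chromosome 5 as a whole and of a shift from 50 Mb on, the test of depth and the run without the third ATUX libraries were chosen only after the result was seen.

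Of 252 values tested for a library far from the others of its drug, 2 stood out. Of so many values some stand out by chance. The test pooled the clones of a drug, so differences between clones, or several outlying libraries at once, can hide an outlier. It did not flag the third ATUX libraries or the third library of Sor9H, which stand apart by other measures. The share of ribosomal RNA counts in the third library of ATUX9D was 0.816%, against 0.5485 to 0.6185% in the other ATUX libraries. The first library of Sor6G had 21820 genes with a count, against 21300 to 21430 in the other Sorafenib libraries.

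PPP2CA was lower in the Sorafenib clones than in the others, and chromosome 5 genes as a set had a median log2 of 0.65 for SMAP against Sorafenib and 0.48 for ATUX against Sorafenib. For SMAP against Sorafenib the medians of the other autosomes had a median of -0.013. TMM scaling holds such a median near 0, so it cannot test for a scaling error. Over whole chromosomes the other autosomes ran from -0.45 to 0.18, while the bin of chromosome 13 from 100 to 125 Mb was at 1.468. A single scaling factor per clone would move all chromosomes alike and would not set chromosome 5 apart. GC content and gene length are argued against. Their trends over all genes had an SD of 0.0358, and the chromosome 5 median was 0.647 with the trends removed and 0.648 before. One shift of the whole chromosome is argued against, since the medians of the first 50 Mb were 1.128 for SMAP and 0.138 for ATUX against Sorafenib (95% intervals over genes 0.954 to 1.277 and 0.048 to 0.217), and those from 50 Mb on 0.57 and 0.55 (0.532 to 0.63 and 0.484 to 0.592). PPP2CA lay at percentiles 71.2 and 76.3 of the 417 genes from 50 Mb on, which is consistent with a shift of that part, and the hypothesis that clones differ in its copy number was not tested on DNA.

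The third libraries of both ATUX clones stood apart from the other 2 of their clone, at a root mean square log2 distance of 0.3393 and 0.2884 from the clone mean against 0.2087 to 0.2544 in the other 19 libraries. Lower depth is argued against, since 3 libraries with lower total counts than either lay closer to their clone mean. A mixture with another clone is argued against, since no other clone explained more than 5.43% of the variance of the difference. RNA degradation could not be decided, with Spearman correlations with gene length across genes of -0.0567 in ATUX8H and -0.291 in ATUX9D, where genes are not independent replicates. Of 580 list members at 5 CPM or more, 15 differed by a log2 of at least 1 in both libraries, all 15 in the same direction, and no biological explanation was tested.

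Clones of the same drug were closer to each other than to clones of another drug. With the median of each 25 Mb bin removed in each clone, the share of the variance between drugs was 83.15%, against 83.27% before and 74.12% for the next partition, over 10971 genes in 129 bins. The bin medians held only 7.58% of the variance between clones, so that removing them could hardly move the share, which cannot decide the question. The 7.58% itself argues against copy number of large segments as the whole source. The drug present at sampling, selection under it and descent from the same resistant culture may each contribute, and they were not tested apart from each other.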

How the results depend on the processing

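The newer edgeR fit, the runs without the third ATUX libraries and without the third library of Sor9H, fry between clones and the 6-library fit with a block were tests chosen only after the result was seen. No gene or list named passed a threshold in the opposite direction, while the median of G2 and mitosis genes for SMAP against Sorafenib was -0.006 without Sor9H. Over the genes named, 8043 values stayed on their side of the threshold, 157 passed it anew and 1067 no longer passed, and over lists 1571, 252 and 104. For ATUX against SMAP, ATUX against Sorafenib and SMAP against Sorafenib, edgeR called 167, 1338 and 2757 genes at an adjusted p of 0.01, and 1187, 2911 and 3839 with a log2 of at least 1. With 21 libraries in place of the sums it called 11251, 12675 and 13068, and with the repeat number as a block 11310, 12712 and 13118, since the spread is then that between libraries. Leaving out a clone gave 560 to 1446, 1430 to 4169 and 2761 to 6811 genes, with fewer clones behind the spread. For ATUX against SMAP, DESeq2 called 3472 genes and limma-voom with the clone as a random block (correlation 0.707) 3933, and the cause was not tested. Between clones, a log2 of at least 1 left 2084 genes for ATUX8H against ATUX9D, 907 for Sor6G against Sor9H, and 1017, 1134 and 1283 for SMAP8D against SMAP9C, SMAP8D against SMAP6G and SMAP9C against SMAP6G. With only the 6 libraries compared the counts in the same order were 5056, 6191, 7345, 7379 and 7900, so that the ATUX pair had the fewest calls. The block changed no clone count by over 1.5 times, with 7713, 5696, 5896, 5870 and 6684 genes, and no call of a gene named between clones. It called 6, 12, 9, 8 and 10 lists, 1 more than without it for SMAP8D against SMAP6G, and 14 of 21 libraries correlated best with a library of their own number. With an estimated correlation, 0, 0 and 0 lists were called between drugs (6, 10 and 11 of 32 with the preset in camera), 2 for ATUX8H against ATUX9D, and 0, 0, 0 and 0 for the other clone comparisons. Fry, which does not compare a list with other genes, called 6, 8 and 12 lists between drugs and 20, 17, 18, 14 and 15 between clones (6, 12, 9, 7 and 10 with the preset), and in either direction 27, 30 and 31 and 29, 28, 29, 29 and 29. For ATUX against SMAP, 12 lists were called with 21 libraries and 7 to 10 with a clone left out, 10 without ATUX8H. The share of the variance between drugs ran from 75.13 to 83.32% with a clone left out, was 66.41% with scaled genes, 84.51% over the 1000 most variable genes and 76.75% with a prior count of 0.5. Without SMAP8D, SMAP9C or SMAP6G it was 79.75, 79.25 and 81.45%, where 15 partitions allow no p below 0.0667. The newer edgeR fit called 2230, 5060 and 6645 genes between drugs, and the planned older fit is the one used throughout. Depth limits genes near 0 counts: folds against 0 counts are bounds, ratios against 1 to 3 counts have counting intervals, and fitted log2 values at few counts depend on the prior count.

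Other splits of the same clones or libraries are too few for a share under 0.05. Each other split also mixes both groups, so that their difference enters the spread within a group and lowers the calls. The low counts of the other splits are therefore no evidence for the real one. For ATUX against SMAP the real split, 1 of 10, gave 1921 genes and the highest other 0 (edgeR, 364 to 2425 genes at an unadjusted p under 0.05). For ATUX against Sorafenib the real split, 1 of 3, gave 4810 and the highest other 0 (256 to 308 unadjusted), and for SMAP against Sorafenib, 1 of 10, 6428 and 0 (69 to 2483 unadjusted). Between clones, each 1 of 10, the real split and the highest other gave 7609 and 99 genes for ATUX8H against ATUX9D, 5561 and 1 for Sor6G against Sor9H, 5798 and 0 for SMAP8D against SMAP9C, 5741 and 0 for SMAP8D against SMAP6G, and 6555 and 0 for SMAP9C against SMAP6G (edgeR, 676 to 2752, 361 to 1275, 354 to 651, 350 to 557 and 379 to 870 unadjusted). Among the 3 other ATUX splits that part all libraries of the same number the highest gave 46.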

Other observations

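The tests of PKD2 and PPM1K were chosen only after the result was seen, and the genes of the first paragraph were picked after their values were seen.

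Some genes called between SMAP8D and another SMAP clone encode chemokines, which were not tested as a group. CXCL6 was at 5.17 ± 0.214 CPM in SMAP8D and 0.285 ± 0.0729 CPM in SMAP6G, and CXCL8 at 12.85 ± 0.699 against 1.87 ± 0.0785 CPM (edgeR adjusted p = 2.97e-09 and 0.000133, 3 libraries per clone). CXCL5 was at 5.20 ± 1.65 against 0.497 ± 0.074 CPM in SMAP9C, and the adhesion molecule ICAM1 at 44.2 ± 4.14 against 13.7 ± 1.39 CPM (edgeR adjusted p = 6.45e-08 and 2.12e-06). The growth factor TGFA went the other way from the ERK output genes it is listed with, at 0.507 ± 0.145 CPM in SMAP8D and 4.47 ± 0.433 CPM in SMAP6G (edgeR adjusted p = 2.98e-10), while ETV5 was at 66.7 ± 5.5 against 17.5 ± 2.73 CPM (edgeR adjusted p = 7.03e-14). In ATUX clones the repressor of epithelial genes ZEB2 was higher than in SMAP clones, at 2.77 ± 0.294 against 0.0902 ± 0.0702 CPM (log2 = 4.91 ± 0.65, edgeR adjusted p = 0.0114), and at 1.95 ± 0.326 CPM without the third ATUX libraries (edgeR adjusted p = 0.0144).

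Pairs of libraries that include the third library of Sor9H had a chi-square per degree of freedom of 13.96 and 15.58, and the pairs with the third libraries of ATUX8H and ATUX9D 29.35, 30.11, 20.3 and 25, against 2.26 to 5.54 in the other pairs. In the third library of Sor9H mitochondrial genes took 3.58% of the counts, against 5.06 and 5.22% in the other 2.

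A hypothesis for the high ABCG2 level in the ATUX clones is a gain of its chromosome segment. The 16 tested genes within 1 Mb had a median log2 of -0.146 for ATUX against Sorafenib and 0.255 for ATUX against SMAP, which argues against a gain of the whole window. Of 2 genes chosen after their values were seen, PKD2, the nearest gene to its left, had a log2 of -0.16 and -0.19, and PPM1K, the nearest to its right, 0.94 and 2.16 without passing the edgeR test (adjusted p = 0.281 and 0.0539). A narrower gain may still be present and was not tested.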
